A study of Mus musculus with 8 samples.

How the data were processed

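The series holds 8 arrays, 4 groups of 2, and the replicates are biological according to the authors' design text. How the control cells were handled, and whether they received the vehicle, is not given in the sources used here. Per the file headers, each array was read with Agilent Feature Extraction 10.7.1.1 in 1 channel, and all 8 arrays lay on 1 slide read in 1 scan, so blocks for slide and scan were not run. Per the file headers, the processed signal is an intensity from which background was subtracted and which was spatially detrended within the array, without scaling between arrays. The values deposited by the authors are in log2 units. They were compared with the processed signal: log2 signal minus the 75th percentile of each array and minus the median of each probe over the 8 arrays gave the authors' values within 0.01 for 99.9% of 56605 probes. Signals from before background subtraction were not needed except for 1 alternative. The files hold no mean pixel signal, so that alternative, normexp with an offset of 50, used the median pixel signal with the median local background. All columns were matched to their sample, with 0 unmatched.

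The tests, gene lists, named-gene rule and most alternative settings were fixed before the data were examined. Spots set as outliers by Feature Extraction were dropped, which left out 323 probes, and replicate spots of a probe were averaged. A probe was kept when it was well above background on both arrays of at least 1 group, 27562 probes in all. Of 56605 probes, 32994 matched a symbol by RefSeq accession in the names given for the mouse assembly GRCm38.p6, which was used for names only, and 23611 did not, 7284 of these with Ensembl transcript names. The array header names the older build mm9, so no coordinates are printed. Among several probes of a gene, the 1 with the highest mean over the 8 arrays was used, a choice that concerned 4625 genes. This gave 21528 genes, 12937 with a symbol and 8591 known by accession or probe only.

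Signals were put on the log2 scale and the 75th percentile of each array was subtracted. Genes were tested with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with a mean per group, lmFit and eBayes. All 8 arrays were in 1 fit with 4 residual degrees of freedom, because 2 arrays per group give little information on spread. P values were two-sided and adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called at adjusted p < 0.05. SE and 95% intervals are those of the moderated fit, and SD is that of the 2 arrays of a group. No exact test of 2 arrays against 2 can reach 0.05.

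The 36 gene lists were written from general knowledge, and the 33 with at least 5 measured genes were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. With an estimated correlation 0 lists were called in any comparison, and the preset value is therefore a condition of every list call. List members were also counted by the gene test, over all genes and adjusted over the list alone. Lists share members: Slc7a11 lies in NRF2 and ATF4, Nqo1 in NRF2 and the aryl hydrocarbon receptor list, Hmox1 in NRF2 and metal response, Atp6v0d2 in V-ATPase and osteoclast, and Atf3 in ATF4 and immediate early genes. Medians are printed, and camera's direction follows the mean of the test statistics. The 2 differed in sign only for lists that were not called: with isorhamnetin the aryl hydrocarbon receptor list (median -0.07, test up), LXR (-0.04, up) and fatty acid synthesis (0.03, down), and with tamarixetin autophagy (-0.01, up) and the aryl hydrocarbon receptor list (-0.02, up). Between the isomers they differed for autophagy (0.03, down), cholesterol synthesis (0.01, down), mitosis (0.01, down), p53 (0.02, down), the aryl hydrocarbon receptor list (-0.05, up) and macrophage markers (-0.02, up). For isorhamnetin against Torin1 they differed for PPAR (0.10, down), and for tamarixetin against Torin1 for the aryl hydrocarbon receptor list (0.02, down), PPAR (0.03, down), immediate early genes (0.09, down) and dendritic and MHC class II genes (0.34, down). The ribosomal list between the isomers had a mean of 0.

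Genes were named by a fixed rule. For each comparison they had an official-looking symbol, adjusted p < 0.05, signal well above background on all 4 arrays and no overlap between the groups. Of these, the 8 largest in each direction were taken for the comparisons with control and between the isomers, and the 4 largest for those with Torin1. Up to 3 lower bounds per direction, up to 4 members per called list and a panel of 16 genes were added. Members of lists named beyond these were chosen after their values were seen, as were the genes called with tamarixetin. Some named genes are left out of the text for length and not by direction. A few others are not reported here. Where a gene was well above background in only 1 of 2 groups, the change is given as a bound, "at least N-fold". It is the mean of the bright group over the mean of the dim group, the latter set on each array to the higher of the lowest signal among probes well above background and the probe's own signal. Of 165 named results with a second probe, 15 were called and had probes that disagreed, among them Atp6v0d2, Kifc2, Rhobtb1, Bcl2l11, Mthfd1, Klhl24 and Ccna2. Disagreement was not counted for results that were not called.

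Shared controls were examined with 100 simulations of unchanged groups set against 2 shared control arrays, all drawn as noise. The measured control arrays were not used in them. As a self-test, known changes were added to simulated arrays in the comparison of tamarixetin with control. These arrays were drawn as noise around a mean per gene, with the same spread in every group. Of genes changed by 0.5, 1 and 2 log2 units, 23.9%, 71.6% and 89.4% were recovered, all with the right sign. Of 127 calls, 4 were false. The measured tamarixetin replicates differed more than those of control, so recovery on the measured arrays may be lower. A shifted list was recovered with 0 others called of 33. Changes below 2-fold may therefore often have been missed here.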

Results

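Transcript levels were measured in J774.1 cells, a mouse macrophage-like line of BALB/c origin, on 8 Agilent arrays labelled with Cy3 alone. There were 4 groups of 2 biological replicates: control, isorhamnetin at 10 µM, tamarixetin at 10 µM and Torin1 at 1 µM. The compounds were given for 6 h, and no time is given for the control cells in the sources used here. Isorhamnetin and tamarixetin are O-methylated forms of the flavonol quercetin. They are isomers that differ in which neighbouring hydroxyl group carries the methyl group. Torin1 inhibits the kinase mTOR. The 75th percentile of the signal was 570 and 498 on the control arrays, 534 and 598 with isorhamnetin, 626 and 558 with tamarixetin, and 559 and 546 with Torin1. The share of probes well above background was 49.0% and 48.7% on the control arrays, 51.1% and 54.1% with isorhamnetin, 43.9% and 44.3% with tamarixetin, and 46.2% and 48.5% with Torin1. In all, 21528 genes were tested, 12937 of them with a symbol. Replicate arrays correlated at r = 0.992 to 0.997. The SD over genes of the log2 difference between replicates was 0.26 in control and with isorhamnetin, 0.44 with tamarixetin and 0.37 with Torin1. The fit used 1 estimate of spread per gene for all 4 groups. The control and isorhamnetin arrays filled 1 row of the slide and the tamarixetin and Torin1 arrays the other. Within each row the groups lay in different columns, control and tamarixetin in columns 1 and 2, isorhamnetin and Torin1 in columns 3 and 4. Position on the slide and group can therefore not be told apart in any comparison. Isorhamnetin and control, and tamarixetin and Torin1, at least shared a slide row.

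The comparison of isorhamnetin with control asked which transcripts changed within 6 h of the compound. Genes of the NRF2 antioxidant list, which encode proteins of glutathione synthesis, quinone reduction and haem breakdown, were higher with isorhamnetin. Slc7a11, which encodes the light chain of the cystine transporter, rose from -0.24 ± 0.07 to 1.37 ± 0.03 (log2 signal relative to the 75th percentile of the array, mean ± SD, n = 2 arrays per group), a log2 fold change of 1.61 ± 0.06 (SE). Gclm, the modifier subunit of glutamate-cysteine ligase, rose from 3.90 ± 0.04 to 5.31 ± 0.02, a log2 fold change of 1.42 ± 0.05. Hmox1, which encodes haem oxygenase, rose by 1.24 ± 0.11, Cbr3, a carbonyl reductase, by 1.15 ± 0.08, and Srxn1, sulfiredoxin, by 1.12 ± 0.10. Nqo1, a quinone reductase that was not well above background in control cells, was at least 2.21-fold higher (adjusted p = 0.0099). Smaller rises were measured for Gclc (0.72), Txnrd1 (0.59), Gsr (0.59), Pgd (0.53) and Abcc1 (0.45). Of the 23 measured members of the NRF2 list, 13 rose and 0 fell over all genes tested, and 17 rose and 0 fell adjusted over the list alone. Its median log2 fold change was 0.53, and the shift passed camera with the preset correlation (adjusted p = 2.83e-19), against adjusted p = 0.22 with an estimated correlation. Slc7a11 and Gclm passed (adjusted p = 0.0044 each) and did so in every alternative analysis except the fit of only the 2 groups, where adjusted p was 0.115 for both. Other calls were lost in fits without single arrays, which also have fewer residual degrees of freedom. Hmox1 had adjusted p = 0.108 and 0.126 without control replicates 1 and 2, 0.119 and 0.127 without isorhamnetin replicates 1 and 2, and 0.0814 without either Torin1 array. Over those same arrays Cbr3 had 0.0678 to 0.101 and Srxn1 0.0534 to 0.119, and Srxn1 had 0.0506 without either tamarixetin array. Nqo1 had 0.07 and 0.0561 without control replicates 1 and 2, and did not pass with normexp background correction (0.52). The NRF2 list shift was called without each single array and under every scaling.

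The amino-acid response and osteoclast lists were also shifted higher with isorhamnetin, though few of their members passed over all genes. Their medians were smaller than that of the NRF2 list, a difference that was not tested. Members of the ATF4 amino-acid response list had a median log2 fold change of 0.16. Over all genes tested 2 of its 25 members rose, Slc7a11, which is also in the NRF2 list, and Atf3 (0.59 ± 0.07, adjusted p = 0.041), and 12 rose adjusted over the list alone. Trib3 (0.57 ± 0.11, adjusted p = 0.11) and Cth (0.52 ± 0.08, adjusted p = 0.0662) did not pass over all genes. The ATF4 list was called (adjusted p = 1.21e-07, against adjusted p = 0.41 with an estimated correlation). The osteoclast list, 8 measured genes, had a median of 0.22 and was called (adjusted p = 0.00324, against adjusted p = 0.41 with an estimated correlation). Ctsk, the lysosomal protease cathepsin K, rose by 0.50 ± 0.05 (adjusted p = 0.0367) and was the only member to pass over all genes, with 4 higher adjusted over the list alone. Atp6v0d2, a subunit of the vacuolar proton pump, had 0.81 ± 0.14 (adjusted p = 0.0835). Atf3 and Ctsk lost their calls without each of the 8 arrays in turn (adjusted p = 0.0601 to 0.205 and 0.0664 to 0.162), while both list shifts were called without each.

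Interferon-stimulated genes were lower with isorhamnetin. Usp18, a protease that removes ISG15 from proteins, fell by 1.42 ± 0.11 on the log2 scale (SE, n = 2 arrays per group), Rtp4 by 1.16 ± 0.10, Oas3 by 1.00 ± 0.09, Ddx58, the RIG-I sensor, by 0.99 ± 0.08 and Ifi204 by 0.79 ± 0.06. Isg15 had -0.68 (adjusted p = 0.0505). The list of 24 measured interferon-stimulated genes had a median of -0.44. Of these, 0 rose and 5 fell over all genes, and 0 rose and 13 fell adjusted over the list alone. The shift was called (adjusted p = 2.68e-12, against adjusted p = 0.41 with an estimated correlation) and was called without each single array. Il1b, the precursor of the cytokine interleukin-1 beta, fell by 1.06 ± 0.08 (adjusted p = 0.0152), Egr1, an immediate early transcription factor, by 0.93 ± 0.10 and Fcgr4, an IgG receptor, by 0.78 ± 0.09. In the NF-kB inflammatory list, which had a median of -0.10, Il1b fell while Ptgs2, cyclooxygenase-2, rose by 0.84 (adjusted p = 0.0164). Over the list alone 2 of its 29 members rose and 5 fell, and the shift was called (adjusted p = 0.00153, against adjusted p = 0.52 with an estimated correlation, 0.0937 with fry and 0.218 without the filter). Tnf had -0.22 and Acod1 -0.08, and neither passed. Without each control, isorhamnetin or Torin1 array in turn, the single-gene calls were lost, with adjusted p of 0.0678 to 0.101 for Usp18, 0.0827 to 0.127 for Rtp4, 0.0869 to 0.152 for Oas3, 0.0792 to 0.124 for Ddx58, 0.0678 to 0.118 for Ifi204, 0.0678 to 0.103 for Il1b and 0.0814 to 0.189 for Egr1. Fcgr4 lost its call without any 1 of the 8 arrays (0.0688 to 0.211).

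A further 5 lists had small negative shifts that passed camera with isorhamnetin. The ribosomal protein list had a median of -0.11 with 0 of 76 members called over all genes or over the list alone (adjusted p = 3.13e-07, against adjusted p = 0.9 with an estimated correlation). Rpl4 had -0.24 and Rps3a1 -0.25. Quantile normalization turned this median to 0.02 (adjusted p = 0.753), and without isorhamnetin replicate 2 it was -0.02 (adjusted p = 0.05). The glycolysis and hypoxia list had -0.15, with Ankrd37 (-0.55 ± 0.07, adjusted p = 0.0487) its only called member over all genes and over the list alone (adjusted p = 2.88e-05, against adjusted p = 0.52 with an estimated correlation). The Ankrd37 call was lost without any 1 of the 8 arrays (adjusted p = 0.0565 to 0.201). Oxidative phosphorylation genes had -0.06, 0 of 39 called either way (adjusted p = 0.02, against adjusted p = 0.9 with an estimated correlation), with Atp5g1 at -0.15, and the call was lost without control replicate 2 (adjusted p = 0.501) and isorhamnetin replicate 2 (0.339). The dendritic and MHC class II list of 5 measured genes had -0.14, 0 called over all genes and 2 lower over the list alone (adjusted p = 0.035, against adjusted p = 0.52 with an estimated correlation), with Cd74 at -0.36. It was lost without control replicate 1 (adjusted p = 0.115) and isorhamnetin replicate 1 (0.184). Cholesterol synthesis genes had -0.08, 0 of 23 called either way (adjusted p = 0.0412, against adjusted p = 0.64 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.115), isorhamnetin replicate 1 (0.188) and either Torin1 array (0.0507). Other settings ended these calls too. Cholesterol synthesis had adjusted p = 0.172 with normexp, 0.0749 with quantile normalization, 0.104 with median scaling, 0.0946 with probes above background on all 8 arrays, 0.0718 in the fit of only the 2 groups, 0.843 without the filter and 0.168 with fry. Oxidative phosphorylation had 0.238 with normexp, 0.95 with quantile normalization, 0.843 without the filter and 0.519 with fry, and the dendritic list 0.0631 with normexp, 0.123 with median scaling, 0.821 without the filter and 0.0694 with fry. Ribosomal proteins had 0.0949 without the filter and 0.423 with fry, and glycolysis 0.0694 with fry.

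Lysosome, V-ATPase, autophagy and MiT/TFE lists were not called with isorhamnetin, with medians of -0.04, -0.06, 0 and 0.01 (adjusted p = 0.213, 0.304, 0.985 and 0.73). Single members passed. Sqstm1, the autophagy receptor p62, rose by 0.76 ± 0.07 (adjusted p = 0.0192), Lipa, lysosomal acid lipase, by 0.83 and Gpnmb, a lysosomal membrane glycoprotein, by 0.54 ± 0.06 (adjusted p = 0.046). The Gpnmb call was lost with normexp background correction (0.18), quantile normalization (0.50) and median scaling (0.48), and without any 1 of the 8 arrays (adjusted p = 0.0725 to 0.184). Sqstm1 lost its call without each control, isorhamnetin or Torin1 array (adjusted p = 0.0814 to 0.122). Flcn, which encodes folliculin, had -0.19 and did not pass. In the fit of all 8 arrays, limma called 119 genes, 92 higher and 27 lower, of which 33 changed at least 2-fold, with 3315 genes at unadjusted p < 0.05. The count fell whenever a single array was left out. It fell even without a tamarixetin or Torin1 array, which changes no isorhamnetin or control value. Such fits have fewer residual degrees of freedom, so the fall does not show that the calls rested on particular arrays. Median scaling gave 13, all of them among the 119, and a fit of only the 2 groups gave 0 with 3138 genes at unadjusted p < 0.05.

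The comparison of tamarixetin with control asked the same of the isomer at the same dose and time. Several genes of the fixed panel had values near 0. Hmox1 had a log2 fold change of -0.06 (95% interval -0.32 to 0.21, n = 2 arrays per group), Sqstm1 0.00 (-0.16 to 0.16), Flcn -0.09 (-0.26 to 0.09), Asns, asparagine synthetase, -0.04 (-0.22 to 0.14) and Tnf -0.02 (-0.23 to 0.20). None of these passed. Larger values that did not pass included Il1b at -0.44 (-0.64 to -0.25, adjusted p = 0.158), Gpnmb at -0.65 (-0.81 to -0.49, adjusted p = 0.0825) and Nqo1 at 0.67 (0.26 to 1.09, adjusted p = 0.224). Gpnmb and Nqo1 were close to background there. The NRF2 list had a median of -0.03 (adjusted p = 0.948), ATF4 -0.06 (0.378), interferon-stimulated genes -0.15 (0.0864), lysosome -0.08 (0.0598), V-ATPase -0.02 (0.9), autophagy -0.01 (0.948), MiT/TFE -0.06 (0.378), glycolysis -0.09 (0.0864) and cholesterol synthesis -0.06 (0.275), and none was called. Some were called in alternative analyses: lysosome, glycolysis and interferon-stimulated genes with probes above background on all 8 arrays (adjusted p = 0.0189, 0.0416 and 0.0189) and with trend and robust eBayes (0.0105, 0.0272 and 0.0272), lysosome with the authors' values (0.024) and glycolysis with the mean of a gene's probes (0.0344). Without tamarixetin replicate 1, lysosome (0.0122), ATF4, cholesterol synthesis and glycolysis (0.0379 each) and interferon-stimulated genes (0.000203) were called. Without the filter all of these lists but MiT/TFE were called: NRF2 (0.00652), ATF4, interferon-stimulated, glycolysis and cholesterol synthesis (0.000522 each), lysosome (3.62e-06), V-ATPase (0.00885) and autophagy (0.00652, with the direction of the test reversed). Most genes added there were near background.

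The only list called with tamarixetin was that of ribosomal proteins, with a median of -0.09 and 0 of 76 members called over all genes or over the list alone (adjusted p = 0.00814, against adjusted p = 0.99 with an estimated correlation). Quantile normalization turned the median to 0.01, and the call was lost without control replicate 2 (adjusted p = 0.452) and without tamarixetin replicate 1 (0.24). It was also lost without the edge rows (adjusted p = 0.0508) and with fry (0.502). The ribosome biogenesis list was called higher with normexp (0.05, adjusted p = 0.016) and quantile normalization (0.04, 0.00528). Without tamarixetin replicate 1 the interferon list gained a call (-0.21, adjusted p = 0.000203), as did lysosome (-0.09, 0.0122) and ATF4, cholesterol synthesis, glycolysis and NF-kB genes (0.0379 each). In limma 17 genes were called, 15 higher and 2 lower, with 2895 at unadjusted p < 0.05. A small number of calls does not show that few genes changed, since the self-test on simulated arrays recovered only 23.9% of changes of 0.5 log2 units. Among the called genes Fmo1 was at least 6.51-fold higher, Ctxn1 at least 4.76-fold and Dpy19l3 at least 3.22-fold, none well above background in control cells. Brsk1 (0.82) was not above background in either group. Of the 15 higher genes, 14 were read from probes in the first 48 spot rows of the array, and without the edge rows 0 genes were called, with 2325 at unadjusted p < 0.05 in limma. The count was 0 without control replicate 1 (2341 at unadjusted p < 0.05) or control replicate 2 (1791), 146 without tamarixetin replicate 1 and 144 without tamarixetin replicate 2. It was 10 without either isorhamnetin array and 20 without either Torin1 array.

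**Figure D1:**
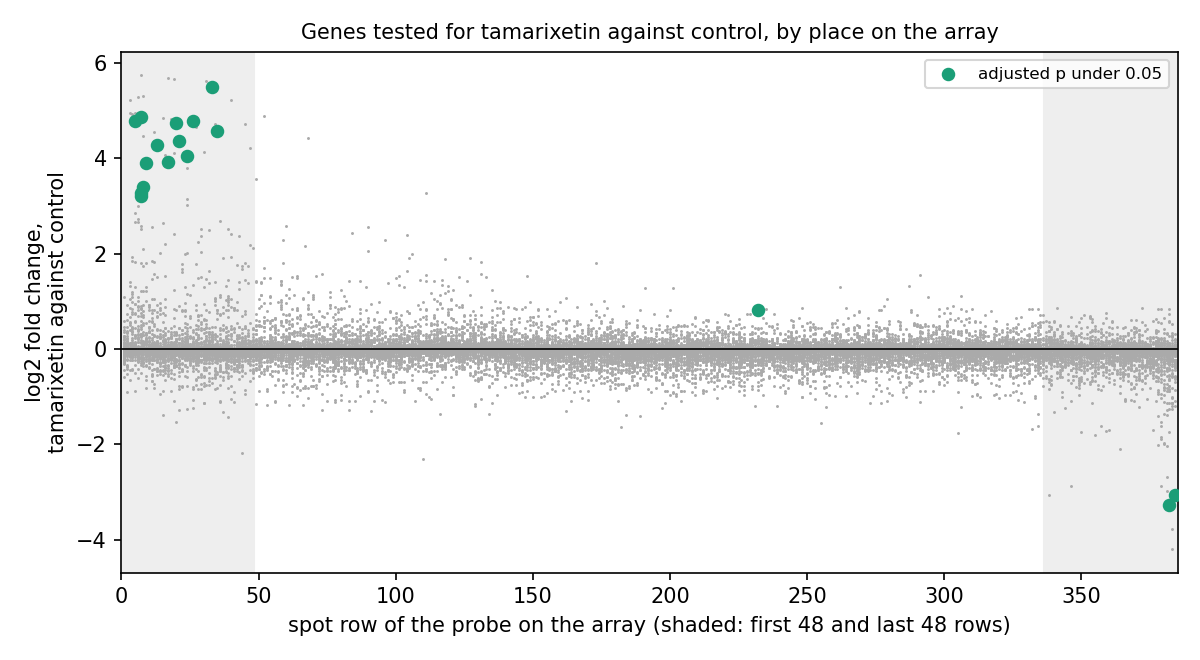
Log2 fold change of tamarixetin against control (y axis) by the spot row of each tested probe (x axis, row number). The first 48 and last 48 rows are shaded, and genes at adjusted p under 0.05 are green.

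The comparison of Torin1 with control asked which transcripts changed after 6 h of mTOR kinase inhibition. Lysosomal genes were higher. Gpnmb rose from -3.24 to 2.60, a log2 fold change of 5.84 ± 0.06 (SE, n = 2 arrays per group). Ctsk rose by 4.45 ± 0.05, and the cathepsins Ctsb and Ctsd by 1.45 ± 0.08 and 1.33 ± 0.06. The chloride-proton exchanger Clcn7 rose by 1.38 ± 0.05 and the hydrolase Naglu by 1.37 ± 0.05. Gm2a, the GM2 activator, fell by 0.68. Of 37 measured lysosome genes, 26 rose and 1 fell, 27 and 1 adjusted over the list alone, with a median of 0.42 (adjusted p = 2.35e-09, against adjusted p = 0.19 with an estimated correlation). Vacuolar proton pump genes also had a median of 0.42. Atp6v0d2 rose by 4.97 ± 0.14, Atp6v1a by 1.48 ± 0.05 and Atp6v1d by 1.01, and 12 of 18 rose and 1 fell, 12 and 2 over the list alone (adjusted p = 7.49e-06, against adjusted p = 0.21 with an estimated correlation).

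Autophagy genes were higher with Torin1 as well, as was the MiT/TFE list, which holds these transcription factors and genes of mTORC1 feedback. Sqstm1 rose by 1.89 ± 0.07 on the log2 scale, Tecpr1 by 1.53 ± 0.12 and Atg2a by 1.07 ± 0.07, and Calcoco1 was at least 2.12-fold higher, while Bnip3, a mitophagy receptor, fell by 1.49. Of 37 autophagy genes 18 rose and 6 fell, the same counts over the list alone, with a median of 0.24 (adjusted p = 0.000648, against adjusted p = 0.28 with an estimated correlation). The folliculin partners Fnip2 and Fnip1 rose by 2.44 ± 0.05 and 1.24 ± 0.06, and Flcn by 0.85 ± 0.07. In the MiT/TFE list 6 of 9 rose and 1 fell, the same over the list alone, with a median of 0.71 (adjusted p = 0.00095, against adjusted p = 0.19 with an estimated correlation). FOXO targets had a median of 0.35. Klhl24 rose by 3.71, Bcl2l11, which encodes the death protein BIM, by 2.03 and Bcl6 by 1.09, and Il7r, the interleukin-7 receptor, was at least 45.3-fold higher. In that list 9 of 17 rose and 2 fell, the same over the list alone (adjusted p = 0.00196, against adjusted p = 0.19 with an estimated correlation).

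**Figure D2:**
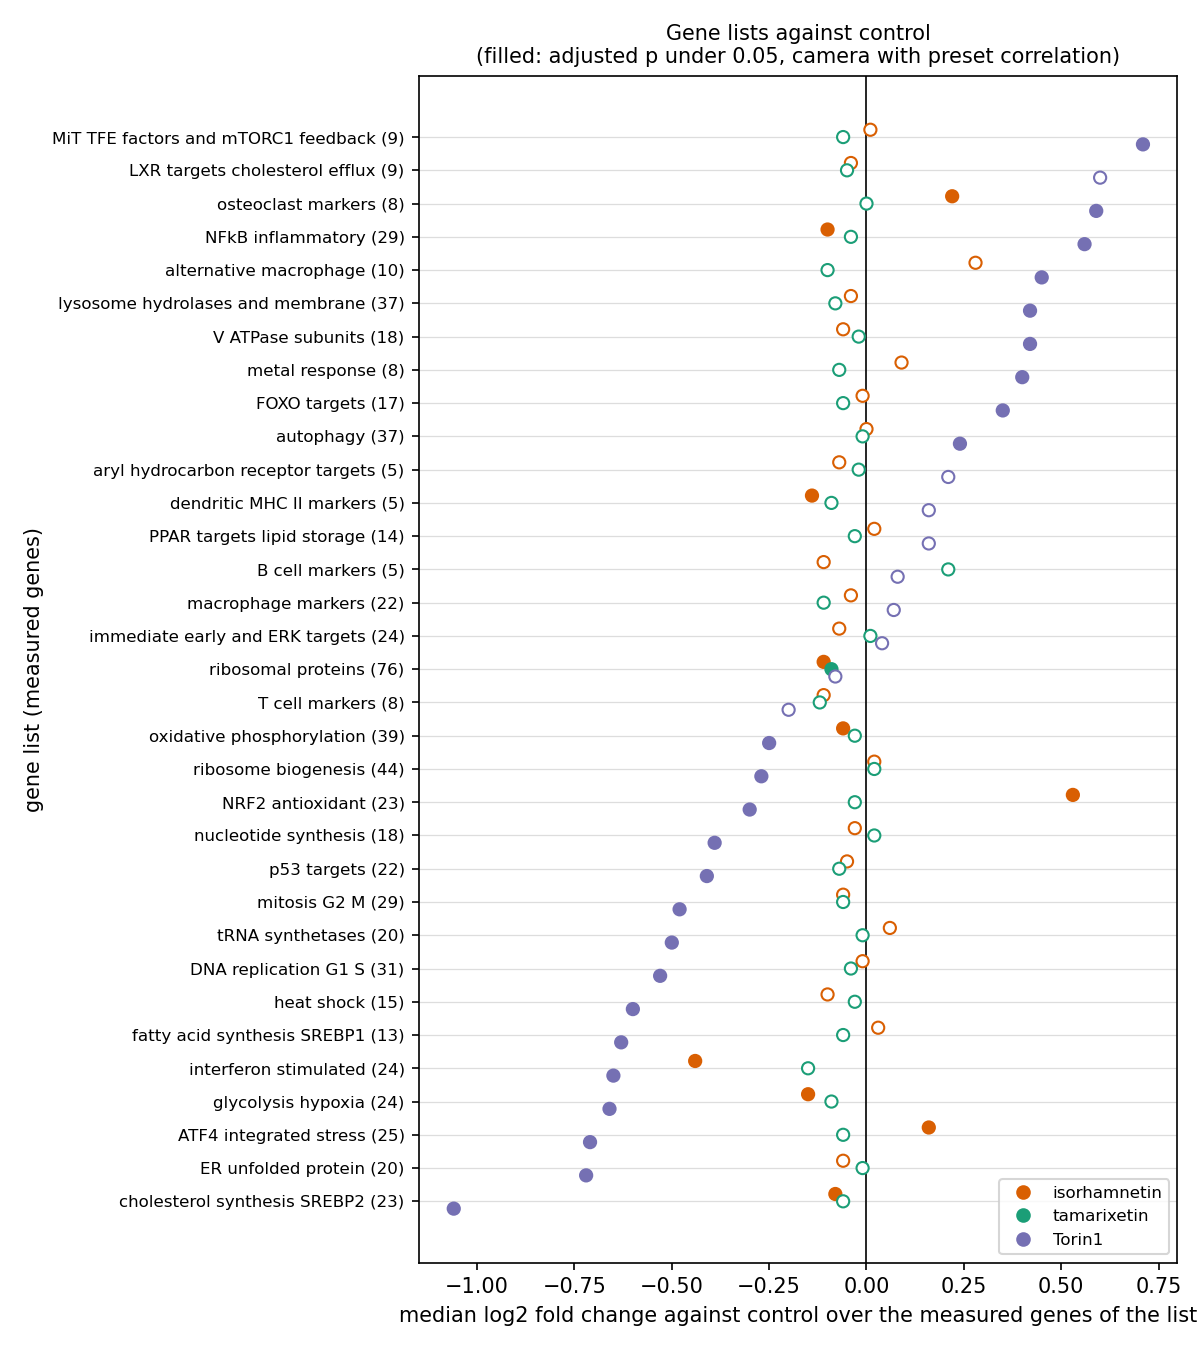
Median log2 fold change against control (x axis) of each of the 33 tested gene lists (y axis, measured genes in brackets) for the 3 compounds. Filled points passed camera with the preset correlation at adjusted p under 0.05.

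Genes of sterol and fatty acid synthesis were lower with Torin1. Every measured member of the cholesterol synthesis list fell, 23 of 23 over all genes and over the list alone, with a median of -1.06 (adjusted p = 5.44e-10, against adjusted p = 0.19 with an estimated correlation). On the log2 scale (± SE, n = 2 arrays per group) Insig1 (-1.70), Idi1 (-1.69 ± 0.05), Msmo1 (-1.60 ± 0.07) and Hmgcs1 (-0.89 ± 0.07) fell. In fatty acid synthesis Scd2, a stearoyl-CoA desaturase, fell by 1.92 ± 0.06, Fads2 by 1.05 and Elovl6 by 1.03. Of its 13 genes 0 rose and 11 fell, the same over the list alone, with a median of -0.63 (adjusted p = 0.000169, against adjusted p = 0.19 with an estimated correlation).

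Genes of the amino-acid response, protein folding and tRNA charging were lower with Torin1. In the ATF4 list Trib3 fell by 3.81 ± 0.11, Chac1, which breaks down glutathione, by 3.33 ± 0.12, Nupr1 by 1.74 and Asns by 0.68, while Atf3 rose by 4.04 ± 0.07. Of 25 members 1 rose and 22 fell, the same over the list alone, with a median of -0.71 (adjusted p = 1.37e-06, against adjusted p = 0.19 with an estimated correlation). Ddit4, which encodes the mTORC1 inhibitor REDD1, fell by 5.40 ± 0.11. The tRNA synthetase genes Cars, Yars and Aars fell by 1.19, 0.90 and 0.86, and of 20 in that list 0 rose and 17 fell, 18 over the list alone, with a median of -0.50 (adjusted p = 3.51e-05, against adjusted p = 0.24 with an estimated correlation). Among unfolded-protein genes of the endoplasmic reticulum, Herpud1 fell by 1.71, the chaperone gene Hspa5 by 1.23 and Creld2 by 1.09, 0 up and 16 down of 20 either way, with a median of -0.72 (adjusted p = 1.86e-06, against adjusted p = 0.19 with an estimated correlation). In the heat shock list Stip1 fell by 0.91 and Hsph1 by 0.88, and Hspa1b was at least 8.37-fold lower. There 0 of 15 rose and 14 fell either way, with a median of -0.60 (adjusted p = 1.73e-05, against adjusted p = 0.19 with an estimated correlation). The NRF2 list had a median of -0.30. Srxn1 fell by 0.89, G6pdx by 0.84 and Me1 by 0.81, while Hmox1 rose by 0.43 (adjusted p = 0.02) and Cbr3 also rose. Of 23 members 2 rose and 15 fell either way (adjusted p = 0.016, against adjusted p = 0.34 with an estimated correlation), and the list was not called with quantile normalization (adjusted p = 0.0771). The Hmox1 call was lost with median scaling (0.24), without control replicate 2 (adjusted p = 0.1), Torin1 replicate 1 (0.0672) and Torin1 replicate 2 (0.0837).

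Cell-cycle and growth genes were lower with Torin1. Among DNA replication genes Tk1, thymidine kinase, fell by 1.52 on the log2 scale, Cdc6 by 1.15 and Rrm2 by 1.14, with 2 of 31 up and 27 down either way and a median of -0.53 (adjusted p = 1.77e-06, against adjusted p = 0.23 with an estimated correlation). Among mitosis genes Aurkb fell by 0.89, Ccna2 by 0.83 and Cdk1 by 0.69, with 0 of 29 up and 23 down, 25 over the list alone, and a median of -0.48 (adjusted p = 1.77e-06, against adjusted p = 0.19 with an estimated correlation). Nucleotide synthesis genes such as Impdh1 (-0.64) and Mthfd1 (-0.67) had a median of -0.39, 1 of 18 up and 14 down either way (adjusted p = 0.00115, against adjusted p = 0.25 with an estimated correlation). Ribosome biogenesis genes such as Nop16 (-0.72) and Noc4l (-0.67) had -0.27, 2 of 44 up and 25 down either way (adjusted p = 0.00196, against adjusted p = 0.36 with an estimated correlation). The glycolysis and hypoxia list had -0.66. Slc16a3, a lactate exporter, and the phosphofructokinase Pfkp each fell by 1.22 and Pfkl by 1.00, while Ndrg1 rose by 1.27. Of its 24 genes 1 rose and 21 fell, 22 over the list alone (adjusted p = 1.88e-06, against adjusted p = 0.21 with an estimated correlation). Oxidative phosphorylation genes such as Atp5g1 (-0.60) and Sdhd (-0.53) had -0.25, 0 of 39 up and 19 down either way (adjusted p = 0.000828, against adjusted p = 0.52 with an estimated correlation). Ribosome biogenesis and oxidative phosphorylation were not called with quantile normalization (adjusted p = 0.312 and 0.24). In the p53 list, with a median of -0.41, Cdkn1a, the cell-cycle inhibitor p21, fell by 2.23, Sesn1 by 1.26 and Phlda3 by 1.23, while Fas rose by 1.61 and Bbc3 by 0.70, and Plk2 was at least 2.25-fold higher. Of 22 members 4 rose and 14 fell, 15 over the list alone (adjusted p = 0.0315, against adjusted p = 0.34 with an estimated correlation). The p53 call was lost without either tamarixetin array (adjusted p = 0.0536), with quantile normalization (0.0631), with median scaling (0.103) and in the fit of only the 2 groups (0.0775). The ribosomal protein list was not called, with a median of -0.08 and 2 of 76 lower over all genes, 0 over the list alone (adjusted p = 0.474). Its sign depended on the scaling: it was called at 0.08 with quantile normalization (adjusted p = 0.00154) and at -0.26 with median scaling (0.0124).

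Inflammatory genes moved both ways with Torin1. The chemokine genes Ccl2 and Ccl7 were higher, Ccl2 by 4.31 ± 0.07 and Ccl7 at least 21.0-fold, and Cd83 rose by 4.06 ± 0.08, Rgs1 by 3.78 ± 0.06, Tnfaip3 by 1.74 and Acod1 by 1.72. Il1b (-2.66 ± 0.08) fell. Of 29 NF-kB list genes 18 rose and 7 fell either way, with a median of 0.56 (adjusted p = 4.92e-05, against adjusted p = 0.19 with an estimated correlation). Interferon-stimulated genes had a median of -0.65. Rtp4 fell by 1.74, Isg15 by 1.45, Ddx58 by 1.24 and Cxcl10 by 1.12, while Ifit2 rose by 0.49. Of 24 members 1 rose and 20 fell, 21 over the list alone (adjusted p = 7.88e-05, against adjusted p = 0.31 with an estimated correlation). Alternative macrophage genes, among them Il10 (2.46), Stab1 (0.93) and Tgm2 (0.93), had a median of 0.45, 5 of 10 up and 1 down either way (adjusted p = 0.0171, against adjusted p = 0.25 with an estimated correlation). The osteoclast list had 0.59. Acp5, tartrate-resistant acid phosphatase, rose by 1.80 and Dcstamp by 0.79, while Ocstamp fell by 0.93, with 5 of 8 up and 1 down either way (adjusted p = 0.00345, against adjusted p = 0.19 with an estimated correlation). Metal response genes such as Mt2 (0.60) and Slc30a1 (0.57) had 0.40, 4 of 8 up and 0 down either way (adjusted p = 0.0176, against adjusted p = 0.19 with an estimated correlation). Without the filter the alternative macrophage and metal response lists were not called (adjusted p = 0.0658 and 0.0941).

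In the fit of all 8 arrays, 10586 genes (49.2% of those tested) were called between Torin1 and control, 4223 higher and 6363 lower, and 1624 of them changed at least 2-fold. The share of called genes that were higher was 39.9%, and 22.5% with median scaling, which shifted the median of all genes from -0.09 to -0.28. Without single arrays the count ranged from 7432 to 10818.

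**Figure D3:**
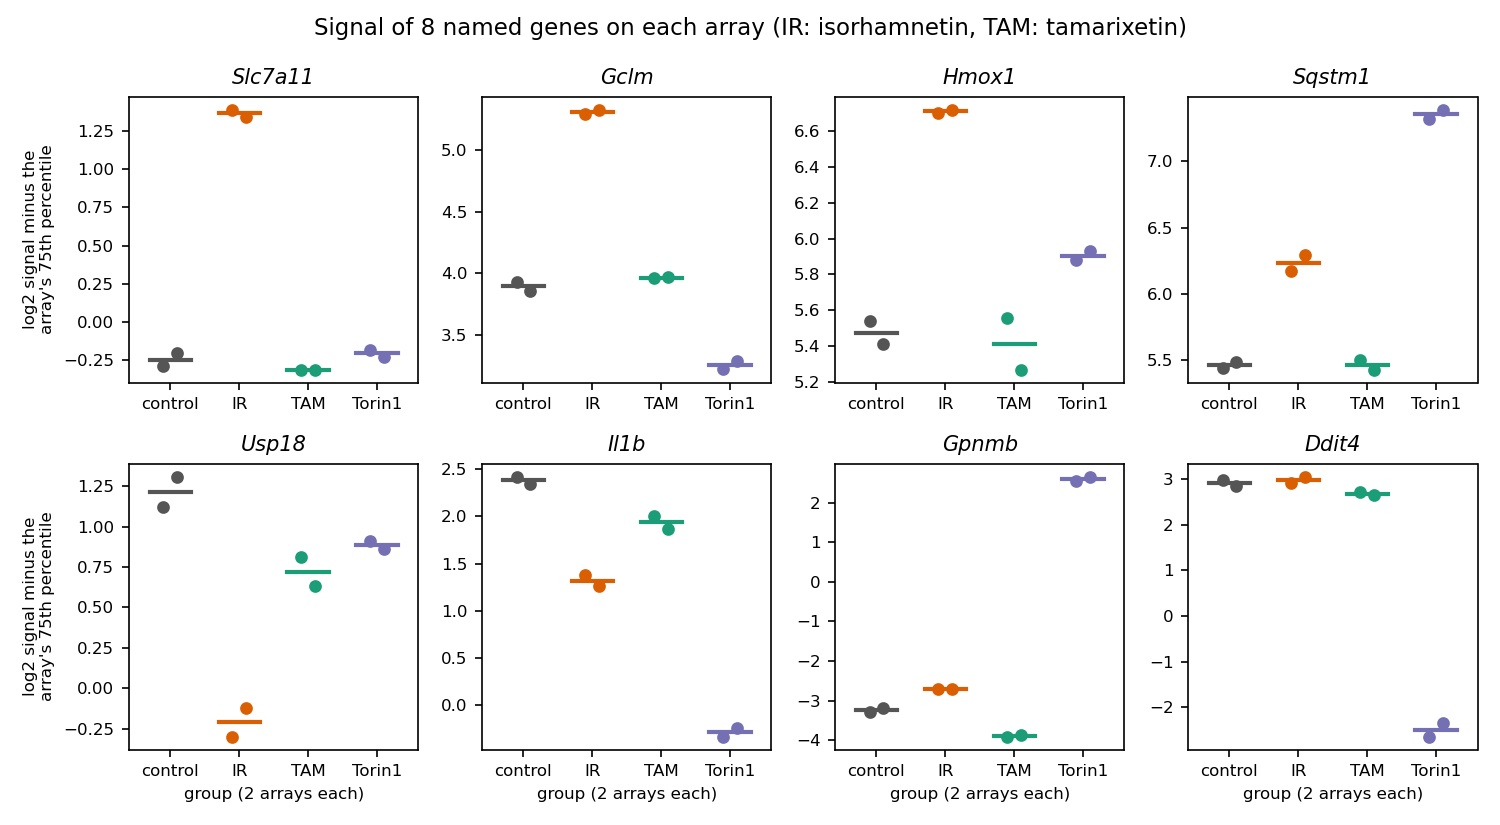
Log2 signal relative to the 75th percentile of each array (y axis) for 8 genes in the 4 groups (x axis). Points are arrays and lines are group means, 2 arrays per group.

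The comparison of isorhamnetin with tamarixetin asked whether the position of the methyl group went with a different response at matched dose and time. NRF2 genes were higher with isorhamnetin than with its isomer. Slc7a11 was higher by 1.68 ± 0.06 (SE, n = 2 arrays per group, adjusted p = 0.00226), Gclm by 1.35 ± 0.05 (adjusted p = 0.00246), Hmox1 by 1.30 ± 0.11 (95% interval 1.03 to 1.56) and Cbr3 by 1.15 ± 0.08. Sqstm1 was higher by 0.76 (0.60 to 0.93), Nqo1 at least 1.21-fold and Gpnmb at least 1.27-fold. All 23 measured members of the NRF2 list had positive values, with a median of 0.59. Of them 13 were higher and 0 lower over all genes, and 17 and 0 over the list alone (adjusted p = 2.42e-24, against adjusted p = 0.14 with an estimated correlation). The ATF4 list had a median of 0.24, with 4 of 25 higher over all genes, Slc7a11, Atf3 (0.69), Pck2 (0.46) and Slc3a2 (0.38), and 15 over the list alone (adjusted p = 5.18e-11, against adjusted p = 0.29 with an estimated correlation). Interferon-stimulated genes had -0.40. Usp18 was lower by 0.93 ± 0.11, Rtp4 by 0.86 ± 0.10, Ddx58 by 0.65 ± 0.08 and Ifi204 by 0.57, these 4 over all genes and 11 over the list alone (adjusted p = 1.63e-13, against adjusted p = 0.36 with an estimated correlation). The osteoclast list had 0.28, with Ctsk (0.48) and Atp6v0d2 (at least 1.67-fold) higher over all genes and 4 over the list alone (adjusted p = 0.0034, against adjusted p = 0.36 with an estimated correlation). A second Atp6v0d2 probe read -0.49. Slc7a11, Gclm and Nqo1 were called without each single array. Hmox1 was not without either control array (adjusted p = 0.055) or isorhamnetin replicates 1 and 2 (0.106 and 0.0929), nor was Cbr3 without isorhamnetin replicates 1 and 2 (0.0722 and 0.0622). Without each control, isorhamnetin or Torin1 array the calls of Sqstm1 (0.055 to 0.0876), Atf3 (0.0723 to 0.105) and Atp6v0d2 (0.0851 to 0.184) were lost. Those of Usp18 (0.0779 to 0.176), Rtp4 (0.0708 to 0.184) and Ddx58 (0.0887 to 0.199) were lost without each array but tamarixetin replicate 2, and that of Ctsk (0.0755 to 0.181) without each of the 8. The 4 lists were called without each single array and under every scaling, and the interferon list was not called without the filter (adjusted p = 0.0815).

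Outside these lists, the C-type lectin gene Clec4n was higher with isorhamnetin than with tamarixetin by 1.48 ± 0.07 (adjusted p = 0.00486), Layn by 1.25 ± 0.08, Ppfibp2 by 1.21 ± 0.06 and Dtx4 by 1.07 ± 0.06. Mxd1, a MYC antagonist, was lower by 1.87 ± 0.15 and Egr1 by 0.85 ± 0.10. Il1b was lower at -0.62 (-0.81 to -0.42, adjusted p = 0.0451), and had -0.63 without the edge rows, where it did not pass (adjusted p = 0.203). The Mxd1 call was lost without either control array (adjusted p = 0.0624) and isorhamnetin replicates 1 and 2 (0.0994 and 0.0672), that of Egr1 without each array but tamarixetin replicate 2 (0.0664 to 0.187) and that of Il1b without any 1 of the 8 (0.0585 to 0.181). Kifc2 had -2.65 from a probe in the edge rows and 0.20 from another. Most genes lay within narrow limits: the 95% interval of the difference was inside 2-fold either way for 18912 of 21528 genes, with a median half-width of 0.23. Examples were Flcn at -0.10 (-0.28 to 0.07), Asns at 0.14 (-0.04 to 0.32), Hmgcs1 at 0.03 (-0.15 to 0.21), Tnf at -0.20 (-0.41 to 0.02) and Acod1 at 0.03 (-0.16 to 0.22). Trib3 was less closely bounded at 0.72 (0.44 to 1, adjusted p = 0.0735).

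A further 7 lists passed camera between the isomers with small medians, and single arrays changed each of these calls. Alternative macrophage genes, with Stab1 higher by 0.63, had a median of 0.26, 1 up over all genes and 4 up and 1 down over the list alone (adjusted p = 0.049, against adjusted p = 0.69 with an estimated correlation). That call was lost without either control array (adjusted p = 0.0613), isorhamnetin replicate 2 (0.225), tamarixetin replicate 2 (0.414) and either Torin1 array (0.0788), and Stab1 lost its own without each control, isorhamnetin or Torin1 array (0.0656 to 0.114). NF-kB genes had -0.08, with Ptgs2 (0.80) and Tnfaip2 (0.70) higher and Il1b lower, 2 up and 2 down over the list alone (adjusted p = 0.0129, against adjusted p = 0.69 with an estimated correlation), lost without isorhamnetin replicate 1 (0.147) and tamarixetin replicate 1 (0.545). Immediate early genes had -0.04, with Atf3 higher and Egr1 lower, 2 up and 3 down over the list alone (adjusted p = 0.0424, against adjusted p = 0.73 with an estimated correlation), lost without isorhamnetin replicate 1 (0.201) and tamarixetin replicate 1 (0.278). Unfolded-protein genes had -0.05 with 0 called either way (adjusted p = 0.045, against adjusted p = 0.73 with an estimated correlation), lost without isorhamnetin replicate 1 (0.275), tamarixetin replicate 1 (0.354) and either Torin1 array (0.0532). Glycolysis genes had -0.04, 0 called over all genes and 1 lower over the list alone (adjusted p = 0.014, against adjusted p = 0.73 with an estimated correlation), lost without isorhamnetin replicate 2 (0.0724) and tamarixetin replicate 1 (0.165). Oxidative phosphorylation genes had -0.03 with 0 called either way (adjusted p = 0.0197, against adjusted p = 0.88 with an estimated correlation), lost without isorhamnetin replicate 2 (0.442), tamarixetin replicate 1 (0.0807) and tamarixetin replicate 2 (0.0725). Ribosomal protein genes had -0.01 with 0 called either way (adjusted p = 0.0461, against adjusted p = 0.88 with an estimated correlation), lost without either control array (0.0613), isorhamnetin replicate 2 (0.07 as the median, adjusted p = 0.261), tamarixetin replicate 2 (0.801) and either Torin1 array (0.0532). Changes of scaling or background ended calls as well: alternative macrophage with normexp (0.139), quantile normalization (0.107) and median scaling (0.136), NF-kB with normexp (0.0551), immediate early with normexp (0.158) and median scaling (0.0612), unfolded-protein with median scaling (0.127), oxidative phosphorylation with median scaling (0.0708), and ribosomal proteins with normexp (0.0819), quantile normalization (0.0681) and median scaling (0.127). Without the edge rows NF-kB (0.0816), immediate early (0.0618), unfolded-protein (0.234) and ribosomal protein genes (0.0816) were not called. With fry only alternative macrophage genes kept a call (the others 0.458 to 0.934).

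Between the isomers, limma called 169 genes, 115 higher and 54 lower with isorhamnetin, of which 66 differed at least 2-fold, with 2726 at unadjusted p < 0.05. Of the 54 lower genes, 36 were read in the first 48 spot rows, and without the edge rows 86 genes were called, 75 higher and 11 lower. The share of called genes that were higher was 68%, 78.8% with quantile normalization and 56.9% with median scaling. The count was 45 without either control array, 40 without isorhamnetin replicate 1, 45 without isorhamnetin replicate 2, 238 without tamarixetin replicate 1, 266 without tamarixetin replicate 2 and 65 without either Torin1 array. A fit of only the 2 groups called 1 gene, with 2127 at unadjusted p < 0.05.

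The comparisons of each isomer with Torin1 asked how far the responses stood apart, at doses that differed. Genes of the amino-acid response were higher with isorhamnetin than with Torin1: Ddit4 by 5.48 ± 0.11 (SE, n = 2 arrays per group), Trib3 by 4.38 and Chac1 by 3.75. Gclm was higher by 2.06, Srxn1 by 2.01, Il1b by 1.60 and Hmox1 by 0.81. Lower were Gpnmb (-5.31), Il7r (-4.95), Ccl2 (-4.37), Cd83 (-4.33) and Sqstm1 (-1.13). The ATF4 list had a median of 1.02 with 23 up and 1 down either way (adjusted p = 1.09e-09, against adjusted p = 0.14 with an estimated correlation), NRF2 0.94 with 20 up and 0 down either way (adjusted p = 3.76e-09, against adjusted p = 0.14), cholesterol synthesis 1.03 with 23 of 23 up either way (adjusted p = 6.62e-11, against adjusted p = 0.14). Lysosome genes had -0.50 with 1 up and 28 down either way (adjusted p = 6.5e-12, against adjusted p = 0.14 with an estimated correlation). Interferon-stimulated genes, at 0.18, were not called (adjusted p = 0.271), with 6 up and 2 down over all genes and over the list alone. They were called higher without the edge rows (0.24, adjusted p = 0.0386) and without the filter (0.16, adjusted p = 0.00911). In all, 9049 genes were called, 5628 higher and 3421 lower, 1299 of them at least 2-fold, and 6217 to 9106 without single arrays. The higher share was 62.2%, and 76.7% with median scaling, where the median of all genes was 0.21. Of the lists 13 were called higher and 10 lower.

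With tamarixetin against Torin1, Ddit4 was higher by 5.17, Trib3 by 3.66 and Chac1 by 3.32, while Ccl2 (-4.51), Ctsk (-4.43), Atf3 (-4.14) and Cd83 (-4.14) were lower (log2, n = 2 arrays per group). Gpnmb was at least 50.4-fold lower and Il7r at least 24.8-fold lower. Cholesterol synthesis genes had a median of 1.04 with 23 of 23 up either way (adjusted p = 3.53e-11, against adjusted p = 0.18 with an estimated correlation), and ATF4 genes 0.64 with 21 up and 1 down, 21 and 2 over the list alone (adjusted p = 3.63e-07, against adjusted p = 0.18). Lysosome genes had -0.54 with 1 up and 28 down either way (adjusted p = 3.53e-11, against adjusted p = 0.18 with an estimated correlation). Interferon-stimulated genes had 0.51 with 15 up and 0 down, 15 and 1 over the list alone (adjusted p = 0.000334, against adjusted p = 0.31 with an estimated correlation). The NRF2 list had 0.29 with 12 up and 2 down either way (adjusted p = 0.0242, against adjusted p = 0.34 with an estimated correlation), a call lost without tamarixetin replicate 1 (0.0631), with quantile normalization (0.0961), without the filter (0.0921), with probes above background on all 8 arrays (0.0684) and without the edge rows (0.0542). In all, 9379 genes were called, 5361 higher and 4018 lower, 1438 of them at least 2-fold, and 6741 to 8785 without single arrays. The higher share was 57.2%, and 68.1% with median scaling, where the median of all genes was 0.14. Of the lists 15 were called higher and 10 lower.

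The last question was whether the compounds changed the same genes. Isorhamnetin and Torin1 called 56 genes higher in both, with 18 expected if independent, and 22 lower in both, with 7.98 expected, while 27 were called in opposite directions. Higher in both were Gpnmb, Ctsk, Sqstm1, Hmox1, Lipa, Mpeg1 and Il7r, and lower in both were Il1b, Usp18, Rtp4, Ddx58 and Egr1. Of the 8 lists called in both, cholesterol synthesis, glycolysis, oxidative phosphorylation, interferon-stimulated and osteoclast genes went the same way, and NRF2, ATF4 and NF-kB genes went opposite ways. With an estimated correlation none of these lists was called, the lowest adjusted p being 0.22 with isorhamnetin and 0.19 with Torin1. Without single arrays the isorhamnetin calls of cholesterol synthesis (control replicate 1, adjusted p = 0.115, isorhamnetin replicate 1, 0.188, either Torin1 array, 0.0507) and oxidative phosphorylation (control replicate 2, 0.501, isorhamnetin replicate 2, 0.339) were lost. Both were also lost with normexp (0.172 and 0.238) and quantile normalization (0.0749 and 0.95), and cholesterol synthesis with median scaling (0.104). Isorhamnetin and tamarixetin shared 0 higher and 2 lower genes, with 0.0641 and 0.00251 expected if independent, and tamarixetin and Torin1 shared 3 higher and 2 lower, with 2.94 and 0.591 expected. The 2 lower genes, the only ones called lower with tamarixetin, were Septin14 and a transcript without a symbol, read in spot rows 384 and 382 at the last edge of the array. Both were well above background in control and not with tamarixetin. Fold changes over all genes correlated at r = 0.36 between isorhamnetin and tamarixetin, 0.39 between isorhamnetin and Torin1 and 0.35 between tamarixetin and Torin1. Noise alone against shared simulated controls gave 0.50 in 100 simulations, a value set by their construction. Changes particular to 1 compound lower r, so values below 0.50 do not show less sharing than shared controls give. The covariances were 0.0366, 0.0721 and 0.0853, above the simulated 0.0224, 0.0223 and 0.0223. For isorhamnetin and Torin1 these simulations, in which no gene changed, gave a mean of 0 genes higher in both and 0 lower in both. With no gene changed hardly any can be called. These zeros therefore do not measure the overlap that shared controls give beside 10586 Torin1 calls. The controls were not split between compounds, since each compound would then have 1 control array, and part of the excess in shared genes may come from them. The comparisons also used the same estimate of spread for each gene, which can add to the overlap beyond that of independent lists. In all 81 genes were called the same way by at least 2 compounds, 2 without control replicate 1, 6 without control replicate 2, 8 without isorhamnetin replicate 1, 9 without isorhamnetin replicate 2, 5 without Torin1 replicate 1 and 10 without Torin1 replicate 2.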

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

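The tests in this part were chosen only after the results were seen. They weigh 3 patterns.

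Genes higher with tamarixetin than in control lay mostly at 1 edge of the array: 93.3% of them were read in the first 48 spot rows, against 12.8% of all tested genes. The same held for probes well above background only on the 2 tamarixetin arrays, of which 43 of 45 (95.6%) lay in those rows, and for 36 of the 54 genes lower with isorhamnetin than with tamarixetin. Of the other probes of these genes outside the edge rows, 0 of 3 were well above background with tamarixetin, which cannot tell a response of the cells from stray signal because such probes may be too weak. Stray signal at the edge of these 2 arrays fits the pattern. What caused it was not tested, and the 1 higher gene outside those rows, Brsk1, was not above background.

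The NRF2 list was higher with isorhamnetin than with tamarixetin, groups that lay in different rows and different columns of the slide. A difference between slide rows could give such a shift, but within 1 slide row, isorhamnetin against control, the median was 0.53, while tamarixetin against control across rows gave -0.03. Dim probes and the higher background floor on the tamarixetin arrays could also give it, but the 22 of 23 members well above background on all 8 arrays had a median of 0.59. Slide columns and group cannot be told apart: Torin1 against tamarixetin, in the same columns of the other slide row, had -0.29, but 43.6% of genes were called there and the response to Torin1 could hide a difference between columns. A response to isorhamnetin that tamarixetin gave less of stays open beside slide columns, and was not tested.

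Genes changed the same way by isorhamnetin and Torin1 could owe this to the 2 shared control arrays. But 57 were higher with isorhamnetin than with tamarixetin and with Torin1 than in control, with 22.6 expected if independent. In these 2 comparisons 48 genes were called in opposite directions. Both used the same estimate of spread for each gene, so genes of low spread can be called in both more often than in independent lists. The excess of higher genes argues against the shared controls as the whole cause. Yet a part may come from them or from the shared estimate of spread. For the lower genes the same overlap showed no excess, with 14 genes and 16 expected. Without the edge rows, 3 of 11 genes lower with isorhamnetin than with tamarixetin were lower with Torin1, with 3.33 expected. The 11 genes lower with both and read outside the edge rows had a median of -0.51 (-0.86 to -0.29), isorhamnetin against tamarixetin, and -0.76 against control. They were chosen for low isorhamnetin arrays, which both comparisons use, so a negative median is partly built in. Shared controls therefore stay open for the lower genes, and the other 11 of the 22 lay in the edge rows. A difference between slide rows cannot enter isorhamnetin against control, which shared a row, and this layout alone argues against slide rows. The 56 genes higher and 22 lower with both, with 18 and 7.98 expected if independent, are the pattern itself and no separate test. A weaker form of the whole Torin1 response is argued against by the 3 of 8 shared lists that went opposite ways, NRF2, ATF4 and NF-kB. None of these was called with an estimated correlation, and NRF2 and ATF4 share Slc7a11. The NF-kB call with isorhamnetin was lost with fry and without the filter, and the NRF2 call with Torin1 with quantile normalization. A weaker Torin1 response together with a separate response of these lists was not tested. Isorhamnetin and Torin1 shared slide columns, which cannot be told apart from a shared response: of 119 genes called between isorhamnetin and control, 66.4% had the same sign in Torin1 against tamarixetin, where the response to Torin1 could hide or mimic a difference between columns.

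Negative-control spots, which should read as background, offer a view of stray signal that the gene tests did not use. Of 308 on each array, 2 were well above background on each control array, 4 and 9 on the isorhamnetin arrays, 8 and 11 on the tamarixetin arrays, and 10 and 5 on the Torin1 arrays. In the first 48 spot rows, which hold 39 of the 308, the numbers were 0 and 0 with isorhamnetin, 7 and 3 with tamarixetin and 3 and 3 with Torin1. Stray signal at that edge could reach the Torin1 arrays too, where 26 of 83 probes above background in that group alone (31.3%) lay in the first rows. Genes called between Torin1 and control did not gather there: 464 of 4223 higher (11%) and 685 of 6363 lower (10.8%) lay in the first rows, against 12.8% of all tested. Of the negative-control spots well above background, 8 of 9 on the second isorhamnetin array, 7 of 11 on the second tamarixetin array and 6 of 10 on the first Torin1 array lay outside both edges. The first and last rows hold only 39 and 40 of the 308, so most spots lie outside the edges by layout alone. Of 18 probes above background in the control group alone, 11 (61.1%) lay in the last 48 rows, and the control arrays enter every comparison with control. The isorhamnetin group alone had 584 such probes, 47 (8.05%) in the first rows and 102 (17.5%) in the last, and these passed the filter through that group. Of the 27 genes lower with isorhamnetin than in control, 12 were read in the first or last 48 rows, and of the 92 higher, 22 were. Between Torin1 and control, 955 of 4223 higher and 1594 of 6363 lower genes were read there.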

How the results depend on the processing

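Most alternatives were fixed before the data were examined. Leaving out the edge rows and the crossed pairing were tests chosen only after the results were seen. Over 480 named-gene results, 8784 of 9441 alternative values were counted as the same, 576 as weaker, 78 as stronger and 3 as reversed. Over 198 list results, 3791 of 4134 were counted as the same, 223 as weaker, 102 as stronger and 18 as reversed. A result called in neither setting was counted as the same even where its sign changed. The reversed counts therefore leave out sign changes among results without a call. Unless the construction shows it, the cause was not tested.

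Background and scaling. Normexp gave 7 genes for tamarixetin against control and 94 between the isomers, correlations of 0.50, 0.34 and 0.28 (isorhamnetin with tamarixetin, isorhamnetin with Torin1, tamarixetin with Torin1), and an overlap of 52. It reversed Nqo1 for Torin1 against control (-0.32). Quantile normalization gave a correlation of 0.32 between tamarixetin and Torin1 and turned the ribosomal list to 0.02, 0.01 and 0.08 for isorhamnetin, tamarixetin and Torin1 against control. Of the genes called for tamarixetin against control, 68.2% (15 of 22) were higher with quantile normalization and 100% (7 of 7) with normexp, in place of 88.2% (15 of 17). Median scaling gave 13 genes for isorhamnetin against control and an overlap of 9, and took away the Torin1 calls of Tnf (0.38), Txnip (0.22) and Tiparp (0.30). The authors' value table gave 117, 17, 10650, 182, 9094 and 9302 genes.

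Filter. What is well above background limits which genes can be compared, and the tamarixetin arrays had the highest floor, with 5th percentiles of 9.78 and 8.80 against 3.27 to 7.63 elsewhere. Without the filter 45380 genes were tested, most of the added ones near background. The counts were then 6 and 12557 for isorhamnetin and tamarixetin against control, 13993 between the isomers, and 19905 and 5680 for isorhamnetin and tamarixetin against Torin1. The correlations were -0.09, which is reversed, 0.12 and 0.51, and the overlap 645. Most lists not called for tamarixetin against control gained a call there. The direction of camera's test reversed for some lists while their median, in brackets, kept its sign: for tamarixetin against control in autophagy (-0.01) and ribosome biogenesis (0.02). Between the isomers it reversed in autophagy (0.02), cholesterol synthesis (0.01), glycolysis (-0.06), oxidative phosphorylation (-0.03), ribosomal proteins (-0.01), ribosome biogenesis (-0.01), mitosis (0.01), NF-kB (-0.11), immediate early (-0.06) and unfolded-protein genes (-0.05), and for isorhamnetin against Torin1 in ribosomal proteins (-0.03). With probes above background on all 8 arrays, isorhamnetin against control had 370 genes and tamarixetin 0, the correlations with isorhamnetin were 0.59 and 0.44, and the overlap was 263.

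Replicate block and pairing. With the replicate number as a block, limma called 4 genes for isorhamnetin against control, 11 for tamarixetin against control and 38 between the isomers, with an overlap of 2. A block uses up residual degrees of freedom, and the labels do not say that the numbers pair cultures. Deviations from group means correlated between -0.131 and 0.0831 across groups, so the numbers carried little pairing. The crossed pairing, on the isorhamnetin and tamarixetin arrays alone, called 0 genes.

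Model and threshold. Trend and robust eBayes called 432, 70 and 255 genes for isorhamnetin and tamarixetin against control and between the isomers, with an overlap of 305. Fits of only the 2 groups called 0 for isorhamnetin against control and 1 between the isomers, with an overlap of 5. Asking for 2-fold as well gave 33 for isorhamnetin and 1624 for Torin1 against control, 66 between the isomers, 1299 and 1438 against Torin1, and an overlap of 15. Spearman correlations with isorhamnetin were 0.51 (tamarixetin) and 0.44 (Torin1). Fry reversed the direction of the aryl hydrocarbon receptor list for tamarixetin against Torin1 (median 0.02). An estimated correlation called 0 lists in place of 94, and fry 103.

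Edge rows. Without them 16986 genes were tested, 0 were called for tamarixetin against control and 86 between the isomers, and the correlations with isorhamnetin were 0.45 and 0.41. Of 88 testable calls for isorhamnetin against control 85 were kept with the same sign, and of 109 between the isomers 85. Kifc2 between the isomers (0.20) and Rpl30 between isorhamnetin and Torin1 (0.23) reversed, each read from another probe.

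Single arrays. Leaving out 1 array gave 5 to 71 genes for isorhamnetin against control, 0 to 146 for tamarixetin, 7432 to 10818 for Torin1, 40 to 266 between the isomers, and 6217 to 9106 and 6741 to 8785 against Torin1. Of the 119 isorhamnetin calls, 5 to 56 were kept with the same sign. The correlations ranged over 0.28 to 0.46, 0.35 to 0.45 and 0.29 to 0.40, the overlap over 2 to 107 and the list calls over 89 to 91. Without isorhamnetin replicate 2 the ribosomal list between the isomers reversed, its range over single arrays being -0.10 to 0.07. These fits have 3 residual degrees of freedom, and a lone array is taken to vary like the others. A first version renewed the background filter on 7 arrays and was changed after its result was seen. It gave 5 to 345, 9 to 783, 7657 to 10685, 42 to 930, 6344 to 9331 and 7180 to 8752 genes.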

Other observations

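The genes and lists in this part were looked at after the tests above, and no tests were added for them. Lipid-handling genes moved both ways with Torin1. Among LXR targets, Abcg1, a cholesterol exporter, rose by 1.48 on the log2 scale (n = 2 arrays per group), Smpdl3a by 1.31, Nr1h3, which encodes LXR alpha, by 1.22 and Abca1 by 1.04, while Lpcat3 fell by 0.66, Apoe by 0.55 and Arl4c by 0.55. The list of 9 had a median of 0.60 and was not called (adjusted p = 0.165), with 5 up and 3 down over all genes and over the list alone. Among PPAR targets, Fabp4 rose by 2.18, Hilpda by 1.59 and Plin2, a lipid droplet coat protein, by 1.30, while Lpl, lipoprotein lipase, fell by 1.13, Ppard by 0.90 and Angptl4 by 0.52. That list had a median of 0.16 (adjusted p = 0.299), with 6 of 14 up and 6 down, 7 and 6 over the list alone. With isorhamnetin, Cd36, a fatty acid and oxidized lipoprotein receptor, rose by 0.55 and Smpdl3a by 0.49, and the LXR and PPAR lists were not called (medians -0.04 and 0.02, adjusted p = 0.752 and 0.799).

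Genes of cell identity and early signalling also moved singly with Torin1. Mpeg1, which encodes the pore-forming perforin-2, rose by 3.86 ± 0.05, Fcgr2b by 1.58, Adgre1, the F4/80 antigen, by 1.44 and Tlr2 by 0.98, while Fcgr1, the high-affinity IgG receptor, fell by 2.23 and Ly86 by 0.52. The macrophage list had a median of 0.07 (adjusted p = 0.0518), 9 of 22 up and 5 down either way, and was called with normexp (adjusted p = 0.0216) and quantile normalization (0.0184). Fry, which does not compare a list with other genes, called the LXR, PPAR, immediate early, macrophage and dendritic lists with Torin1 (adjusted p = 0.000271, 0.00211, 0.000562, 0.000145 and 0.000145). Among immediate early genes Dusp4 and Myc each rose by 1.98 and Egr3 by 1.57, while Egr1 fell by 1.93, Ier3 by 1.39 and Dusp2 by 1.16 (median 0.04, adjusted p = 0.159, 10 of 24 up and 7 down, 11 and 8 over the list alone). H2-Eb1 rose by 1.63 while H2-DMa fell by 1.37 and Cd74 by 0.55 (dendritic and MHC class II list, median 0.16, adjusted p = 0.449). Markers of other lineages were measured near background in part: the T cell list had a median of -0.20 with Cd4 at -0.78 (adjusted p = 0.663), the B cell list 0.08 with Cd22 at 0.56 (adjusted p = 0.445), and the aryl hydrocarbon receptor list 0.21 (adjusted p = 0.689). With isorhamnetin these 3 had -0.11, -0.11 and -0.07 (adjusted p = 0.739, 0.678 and 0.907). The lists of neutrophil and mast cell, fibroblast, and epithelial and endothelial markers had 2 measured genes each and were not tested.

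Of the 56 genes higher with both isorhamnetin and Torin1, 33 were also called higher with isorhamnetin than with tamarixetin. In the edge rows 11 of the 56 were read, beside 955 of all 4223 genes higher with Torin1 than in control.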
